A study of Mus musculus with 7 samples.

How the data were processed

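Per the labels, lung epithelial cells of C57BL/6 mice were released with collagenase, Dispase II and DNase I. They were sorted as propidium iodide-negative, Epcam-positive cells without CD31, CD45, Ter119 or CD146, and amplified polyadenylated RNA was read by 3' SAGE sequencing on an Ion Proton. The deposited values are a signal per gene and library, tag counts divided by 1 factor per library by the authors. This unit was read from the values themselves, since each column returned whole numbers of reads once divided by its smallest step, for 100% of genes within 0.01 reads (largest distance 3.4e-05). The columns sum to between 918538.5 and 1058211. Per the submitters' processing notes, Bowtie2 2.2.5, R 3.4.0 and the mm10 build were used. Which program counted the tags, with which annotation, filters and scaling method, is not given in the sources used here.

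The 7 libraries form 5 stages, 3 of them with 1 library and 2 with 2. The labels do not say whether libraries of a stage came from different animals, litters or sorts, so each p-value measures only the spread between these samples. Of 21121 genes, 12964 passed the filterByExpr rule by stage on the recovered reads and were tested. Changes were tested with limma-trend on log2(value + 1), with all 7 libraries in 1 fit with a coefficient per stage, robust variance estimates and 2 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The pseudocount of 1 pulls log2 changes of genes with few reads towards 0, and ratios of means do not carry it. A stage with 1 library was assumed to vary like the replicated stages. The design fixed before the data were examined named edgeR for counts and limma-trend for a normalized unit. The values turned out to be scaled, so limma-trend was used, and edgeR quasi-likelihood tests on the recovered reads were added once the files had been seen. For the same reason E15.5 and E13.5 were compared on log2(value + 1) and not with the edgeR prior count first planned.

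The stage contrasts, the gene lists and the rule for naming genes were fixed before the data were examined. Named genes have an adjusted p under 0.05, libraries that do not overlap between the stages, a mean of at least 100 in the higher stage and no predicted or clone symbol. Of these the 8 largest log2 changes in each direction were named for P56 against E18.5, and the 6 largest for the other comparisons. Up to 4 members of each list with the smallest p were named too, with the genes that check the sort. Not every gene that the rule names is reported here. Genes named outside the rule are marked as chosen after the values were seen. Lists with at least 5 tested members, 28 of 30, were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. Each list's members were also adjusted over the list alone. Where a stage had 0 reads, a floor of 3 reads gave a lower bound on the ratio. Where it had 1 to 3 reads, a 95% counting interval is given. Bounds and intervals cover counting error only. A tag near the 3' end does not measure genes equally, so levels were compared within a gene and not between genes.

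Both tools were tested on simulated data with known changes, a single data set per comparison. In each, 87 genes were changed 2-fold, 67 4-fold and 66 8-fold among 12964, none of them with a low mean value. Counts were drawn with a spread set by expression level alone, without a spread particular to each gene. On that account the rates may look better than those in the real data. The changed genes were also far fewer than the 1843 that limma called in P56 against E18.5. The same holds for the 3779 called in E18.5 against the early stages. For those comparisons the rates come from a setting unlike the data. For P56 against E18.5 limma recovered 28.7% of 2-fold, 83.6% of 4-fold and 97.0% of 8-fold changes with 2.68% false calls. For E18.5 against the early stages the values were 33.3%, 82.1% and 90.9% with 5.26%. For P14 against E18.5 they were 14.9%, 62.7% and 92.4% with 7.20%, and for P56 against P14 10.3%, 64.2% and 93.9% with 6.56%. In the same order of comparisons edgeR recovered 25.3%, 80.6% and 95.5% with 2.11% false calls, 28.7%, 82.1% and 81.8% with 5.63%, 14.9%, 67.2% and 90.9% with 8.53%, and 14.9%, 64.2% and 89.4% with 4.96%. A simulated list of 20 genes, each raised 2-fold, had camera p = 6.67e-28, 5.92e-17, 1.38e-13 and 3.63e-11 at the preset correlation, in the same order. With an estimated correlation camera gave p = 0.00717, 0.0118, 0.0536 and 0.0186, before adjustment over lists. In that setting camera tests on the 2 residual degrees of freedom of the fit. A call lost there therefore does not by itself show that a list was unchanged, nor that its genes were strongly correlated. Other scalings, filters, pseudocounts, tests, a replicate block and leaving out each library were also tried. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.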

Results

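The series followed the transcriptome of mouse lung epithelial cells across 5 stages of development, 3 before birth and 2 after. Cells from C57BL/6 lungs were sorted by flow cytometry as living cells that carried Epcam, a surface protein of epithelial cells, and lacked the blood and vessel surface proteins CD31, CD45, Ter119 and CD146. RNA was measured by 3' SAGE sequencing, which reads a short tag near the 3' end of each transcript, so that 1 tag stands for 1 amplified transcript whatever its length. There were 7 libraries: 1 each at embryonic day 13.5 (E13.5), E15.5 and postnatal day 14 (P14), and 2 each at E18.5 and P56. Each library listed 21121 genes, of which 15268 to 16104 had at least 1 read. Values are scaled tag counts, with 1 read worth 0.236 to 0.385 units. Depth was 3895740 reads at E13.5, 2559927 at E15.5, 2617913 and 2808678 at E18.5, 3818722 at P14 and 3587970 and 3227687 at P56. The most abundant gene in every library was Eef1a1, a translation elongation factor, with 3.96% of the reads in P56 replicate 2 (95% exact binomial interval 3.94 to 3.98%) and 7.14% in E18.5 replicate 2 (7.11 to 7.17%).

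Genes that check the sort were looked at first. Epcam lay between 55.8 and 213 in the 7 libraries, Cdh1, which encodes E-cadherin, between 104 and 286, and Nkx2-1, a transcription factor of lung and thyroid epithelium, between 502 and 1969. Ptprc, which encodes CD45, had 0 to 4 reads per library, as did Pecam1, which encodes CD31. Mcam, which encodes CD146, had 26 reads at E13.5, 14 at E15.5 and 0 to 4 in each of the other libraries. Hbb-bs, an adult beta globin gene, had 0 reads in E18.5 replicate 1 and 61 in E18.5 replicate 2. Over the listed members, immune cell markers took 7.64e-05% to 0.00333% of the reads and endothelial markers 0.00608% to 0.0240%. Mesenchymal markers took 0.285% at E13.5, 0.155% at E15.5 and 0.0151% to 0.0362% later. Most of the early mesenchymal share came from 1 gene, Vim. It stood at 2564 of 2627.5 units at E13.5 and at 1193 of 1420.9 at E15.5, so that share does not describe the other markers.

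The libraries lay in the order of age along the first principal component of log2(value + 1), which held 55.2% of the variance. Its scores ran from -135.07 at E13.5 and -80.83 at E15.5 to 17.92 and 21.38 at E18.5, 48.43 at P14 and 64.17 and 64.01 at P56. On the second component, with 22.5% of the variance, the E18.5 libraries stood at -62.23 and -71.64 while E13.5 stood at 33.14 and P56 at 43.84 and 50.29. Libraries of the same stage lay close together but differed by more than counting noise: the chi-square per degree of freedom of their counts over genes was 9.36 at E18.5 and 7.21 at P56, against 28.4 to 161 for libraries of different stages. The median absolute log2 difference between replicates, over 6807 genes with a mean value of at least 10, was 0.32 at E18.5 and 0.26 at P56.

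**Figure D1:**
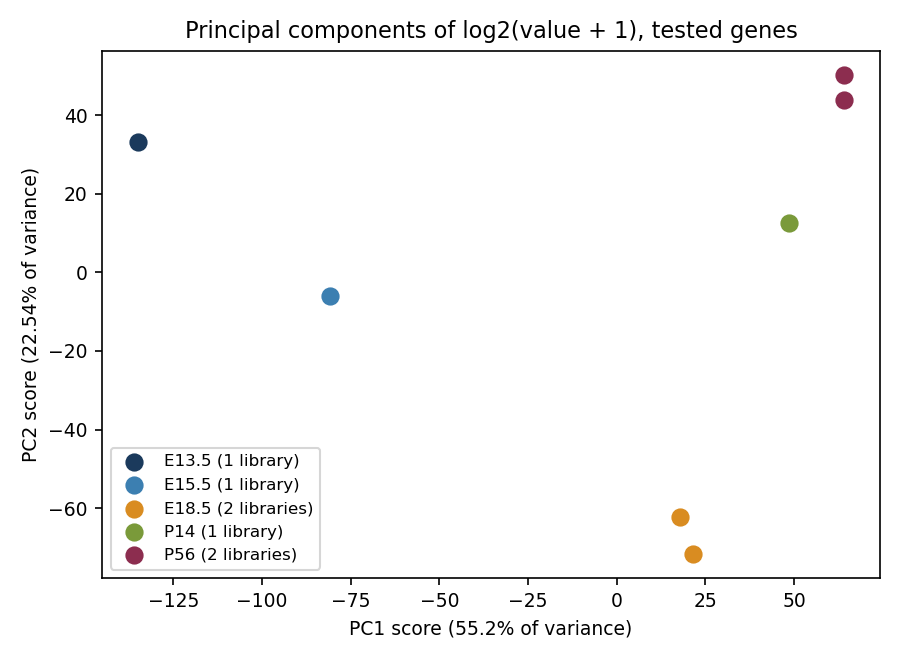
Scores of the 7 libraries on the first (55.2% of variance) and second (22.5%) principal components of log2(value + 1), 1 point per library and coloured by stage. Both axes are unitless scores; E13.5 lies at -135.07 on the first component and P56 at 64.17 and 64.01, and the E18.5 libraries are lowest on the second at -62.23 and -71.64.

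Adult epithelial cells at P56 were compared with late fetal cells at E18.5, the step with 2 libraries on each side, to show which transcripts distinguish the mature from the prenatal lung epithelium. MHC class II, lysozyme and surfactant transcripts rose, and most alveolar type 1 markers and several imprinted fetal transcripts fell. H2-Eb1, a chain of the MHC class II molecule that presents antigen to helper T cells, rose from 5.37 ± 5.47 (SD, n = 2) to 4315 ± 766, an 803-fold ratio of means (log2 change 9.72, SE 0.574, adjusted p = 0.000125). Lyz2, a lysozyme that attacks bacterial walls, rose 44.8-fold from 69.7 ± 1.09 to 3122 ± 693 (adjusted p = 5.45e-05). Sftpc, the surfactant protein made by alveolar type 2 cells, rose 5.66-fold from 3659 ± 416 to 20718 ± 1030 (adjusted p = 0.000201). Clic5, a chloride channel family member abundant in the thin type 1 cells that carry gas exchange, fell 12.6-fold from 2917 ± 243 to 232 ± 7.93 (adjusted p = 7.17e-05). H19, an imprinted non-coding RNA of fetal tissues, fell from 373 ± 33.4 to 0 reads in both P56 libraries, at least 821-fold lower (adjusted p = 5.56e-06).

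The largest rises among abundant genes included 4 genes of the MHC class II system. Positions here and below are on GRCm38/mm10, from the GENCODE vM21 annotation. H2-Eb1 lies on chromosome 17 at 34305867 to 34316674, beside H2-Aa (34282744 to 34287823) and H2-Ab1 (34257689 to 34269419), and all 3 are protein-coding, as are the other genes placed here unless called non-coding. H2-Aa rose from 0 reads to 200 ± 21.9, at least 349-fold (adjusted p = 5.75e-05). H2-Ab1 rose from 0 reads to 189 ± 49.8, at least 327-fold (adjusted p = 7.17e-05). Cd74, the invariant chain that escorts class II molecules (chromosome 18, 60803848 to 60812652), rose from 5.91 ± 1.44 to 675 ± 42.0. Reads of MHC paralogs can be shared, so single H2 genes are uncertain. Cox6a2, a subunit of cytochrome c oxidase best known from muscle, rose 194-fold to 1080 ± 246, and Gdnf, a neurotrophic growth factor, 87.0-fold to 265 ± 41.4. Itih4, an acute phase protein gene, rose 62.6-fold and the neutrophil chemokine gene Cxcl3 72.0-fold, although Cxcl3 reads can be split with its close copy Cxcl2. Among the largest falls, Fstl1, a secreted glycoprotein gene (chromosome 16, 37776873 to 37836514), went from 5552 ± 20.8 to 29.8 ± 8.72 and Msln, which encodes the surface protein mesothelin, from 641 ± 130 to 2.50 ± 1.70. Rian (chromosome 12, 109603940 to 109661716), a non-coding RNA of the imprinted Dlk1 domain, fell from 3073 ± 314 to 17.3 ± 8.91, and Dlk1 itself (109452823 to 109463336) from 174 ± 13.2 to 0 reads, at least 383-fold lower. Aqp1, a water channel gene, also fell to 0 reads, at least 252-fold lower. Igf2bp3, an RNA-binding protein gene of fetal tissues, fell to 1 read in the P56 libraries together, a ratio of 723 (counting interval 129 to 28600), and Tecrl to 3 reads, a ratio of 247 (84.0 to 1200). Each of these 16 genes had an adjusted p between 5.56e-06 and 0.000208 and non-overlapping libraries.

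Markers of the 2 alveolar cell types moved in opposite directions. Of 21 tested type 2 markers 18 rose, with a median log2 change of 1.87, and Ctsh, a lysosomal protease gene, fell by 0.70 on the log2 scale (19 rose and 1 fell adjusted over the list alone). Sftpa1, another surfactant protein gene, rose from 439 ± 46.0 to 5717 ± 1200. Lyz1, which can share reads with Lyz2, rose 16.9-fold to 6605 ± 285. The list stood above other genes by camera (adjusted p = 1.27e-12), a call that was lost at adjusted p = 0.241 with an estimated correlation. Of 22 tested type 1 markers 19 fell, 20 adjusted over the list alone, and none rose, with a median log2 change of -2.48. Cav1, the scaffold of caveolae, fell 31.4-fold, Rtkn2 22.8-fold and Lmo7, an actin-binding adaptor gene, 6.16-fold. The exceptions were the water channel gene Aqp5 at 2056 ± 177 and 2772 ± 322 (log2 change 0.43, adjusted p = 0.172), Cldn18, a tight junction gene, at 12687 and 8893 (adjusted p = 0.0734, and 0.0414 with edgeR), and Igfbp2 at 2.67 and 1.40. The type 1 list had a camera adjusted p = 8.83e-16, and adjusted p = 0.241 with an estimated correlation. Type 2 markers took 1.53% and 1.44% of all reads at E18.5 and 6.69% and 7.22% at P56, and type 1 markers 3.46% and 4.02%, then 1.47% in P56 replicate 1.

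**Figure D2:**
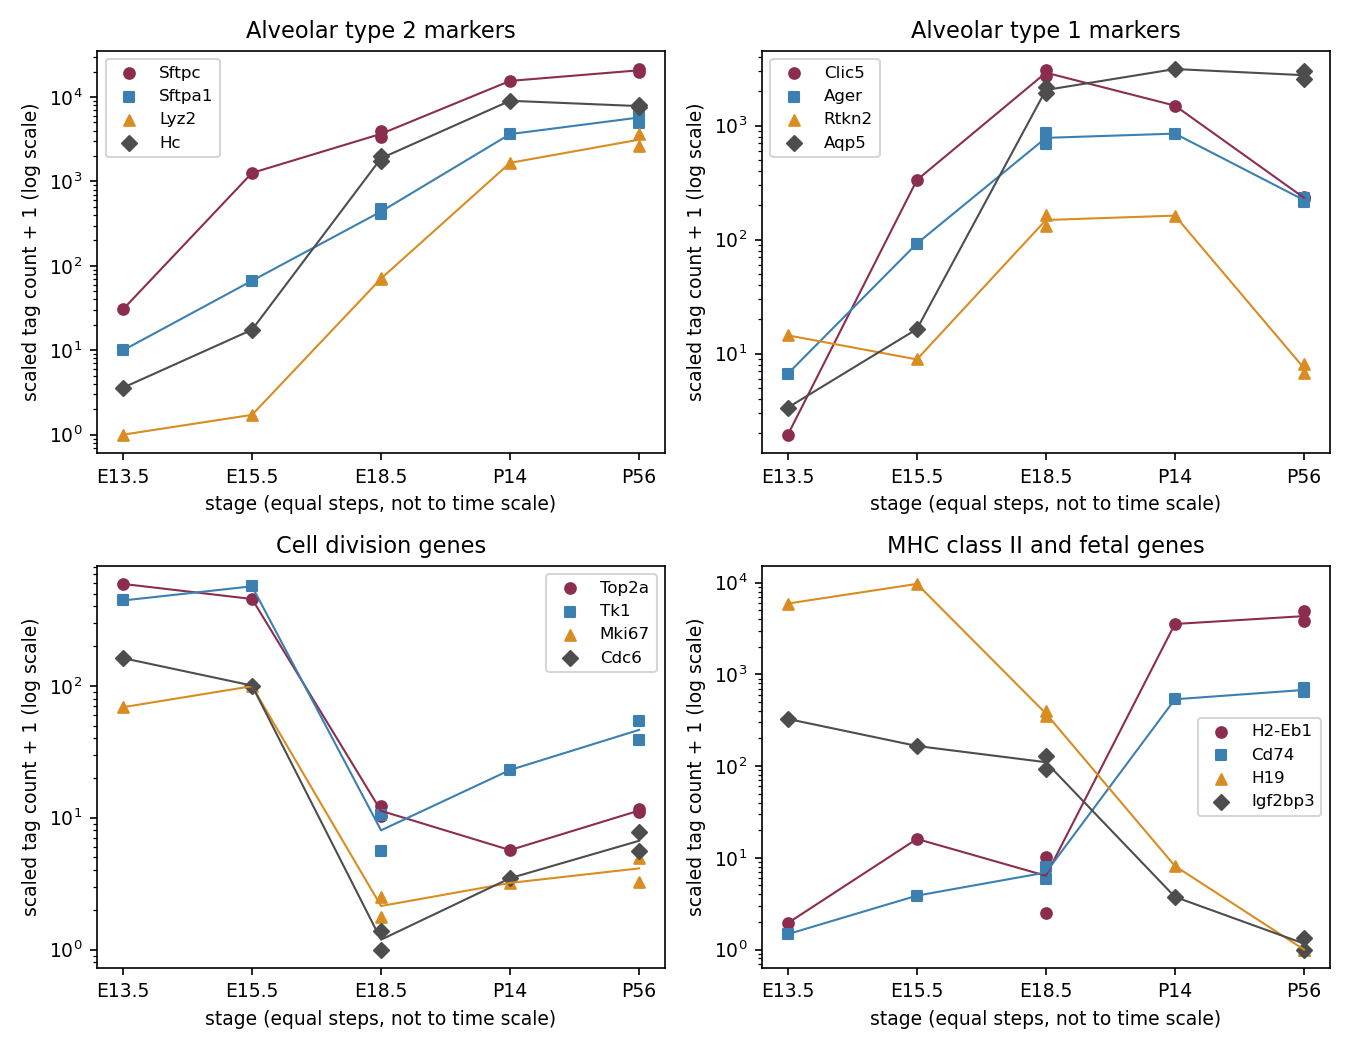
Scaled tag count + 1 on a log axis for 16 genes at the 5 stages, with 1 point per library and lines through the stage means, stages drawn at equal steps. Sftpc reached 20718 at P56, Clic5 went from 2917 at E18.5 to 232 at P56, H2-Eb1 from 5.37 to 4315, and Top2a was at 591 and 454 at E13.5 and E15.5 and 10.3 at E18.5.

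Many airway secretory and defence genes rose as well. Of 12 tested club cell markers 8 rose, and Cldn10, a tight junction gene, fell 42.2-fold (8 rose and 2 fell adjusted over the list alone; median log2 change 1.42). Scgb1a1, the main secretory protein of club cells, rose 20.8-fold to 308 ± 50.2, the carbonyl reductase gene Cbr2 8.10-fold and the haptoglobin gene Hp 8.10-fold. The club cell list had a camera adjusted p = 0.00518, and adjusted p = 0.241 with an estimated correlation. All 8 tested MHC class II genes rose, also adjusted over the list alone, with a median log2 change of 5.78 (camera adjusted p = 7.23e-08; adjusted p = 0.241 with an estimated correlation). Of 14 MHC class I genes 5 rose and none fell (8 and 0 adjusted over the list alone; median 1.44; camera adjusted p = 0.00169, and adjusted p = 0.241 with an estimated correlation). The 5 were H2-K1, B2m, the peptide transporter gene Tap2 at 3.52-fold, the immunoproteasome gene Psmb8 at 3.46-fold, and Psmb9. Of 16 innate defence genes 13 rose, 14 adjusted over the list alone with 1 fall, with a median of 2.93 (camera adjusted p = 8.34e-10; adjusted p = 0.241 with an estimated correlation). The innate defence list shares the lysozymes and other members with the type 2 list, so their rises are not fully separate results. Beyond the lysozymes, Wfdc2, a secreted antiprotease-like gene, rose 8.01-fold from 59.3 to 475. Of 19 xenobiotic and antioxidant enzyme genes 9 rose and the alcohol dehydrogenase gene Adh1 fell (10 and 1 adjusted over the list alone; median 1.04; camera adjusted p = 0.000321, and adjusted p = 0.241 with an estimated correlation). Aldehyde oxidase Aox3 rose 29.0-fold, the epoxide hydrolase gene Ephx1 24.1-fold, and the cytochrome P450 gene Cyp2b10 went from 2 reads at E18.5 to 175 reads at P56, a ratio of 69.6 (counting interval 19 to 579).

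Fetal growth genes fell in part. Of 17 tested imprinted growth genes 10 fell and 3 rose, the same counts as adjusted over the list alone, with a median log2 change of -1.52 (camera adjusted p = 2.74e-05; adjusted p = 0.241 with an estimated correlation). Besides H19 and Dlk1, the non-coding RNA Meg3 fell 69.0-fold from 1788 ± 118 to 25.9 and the cyclin-dependent kinase inhibitor gene Cdkn1c 9.49-fold. The 3 that rose were Peg10 (4.80-fold), Impact (2.39-fold) and Slc38a4 (4.49-fold). Of 10 fetal RNA-binding and let-7 target genes 5 fell and none rose (8 and 0 adjusted over the list alone), with a median of -1.38, or -1.62 with genes at 0 reads set at their bounds (camera adjusted p = 2.47e-05; adjusted p = 0.241 with an estimated correlation). They were Igf2bp3, Igf2bp1 (at least 36.0-fold lower), Igf2bp2 (7.70-fold), Hmga2 (at least 6.71-fold lower) and Hmga1. Of 22 DNA replication genes 6 rose, also adjusted over the list alone, and none fell (median 0.599, or 0.463 with bounds; camera adjusted p = 0.00578, and adjusted p = 0.241 with an estimated correlation). These were Mcm3, Cdc6, Fen1, Pola1, the primase gene Prim1 from 10.7 to 47.4 and the thymidine kinase gene Tk1 from 7.02 to 45.3, levels below the 418 and 443 of those genes at E13.5. No mitosis gene of 23 was called by limma or by edgeR (median 0.115, camera adjusted p = 0.464).

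Many mesenchymal markers and the epithelial genes Krt19 and Cldn4 were also lower at P56. Of 13 tested mesenchymal markers 7 fell and Dcn, which encodes decorin, rose 17.6-fold (8 fell and 2 rose adjusted over the list alone; median -1.49, or -1.80 with bounds; camera adjusted p = 0.00202, and adjusted p = 0.241 with an estimated correlation). The elastin gene Eln fell 54.6-fold from 49.8, the collagen gene Col1a1 36.1-fold from 32.3, the intermediate filament gene Vim 2.87-fold, and Tcf21 to 2 reads, a ratio of 36.5 (9.65 to 308). Of 12 epithelial identity genes Krt19, a simple epithelial keratin (chromosome 11, 100140810 to 100148665), fell 8.78-fold from 7799 ± 415 and the tight junction gene Cldn4 58.7-fold, with 4 falls adjusted over the list alone (median -0.319; camera adjusted p = 0.046, and adjusted p = 0.494 with an estimated correlation). The tip progenitor genes Sox9 and Shh fell 37.6-fold and 4.94-fold. Etv5, a target of FGF signalling, and the chaperone gene Clu rose 4.27-fold and 6.69-fold, and their list was not called (median 0.00, adjusted p = 0.797). Fatty acid and phospholipid synthesis genes had 7 rises, led by the elongase Elovl1 (16.5-fold) and the desaturase Scd1 (4.95-fold, to 8286 ± 671), and 1 fall, Scd2, which can share reads with Scd1. That list was not called (adjusted p = 0.0552). Ion and water transport genes were not called either (adjusted p = 0.0916), with 2 rises, Slc12a2 and Slc26a4, and 5 falls, among them the sodium channel subunit gene Scnn1g (33.2-fold), Aqp1, Scnn1b, Ano1 and Fxyd3. The 5 tested immune markers gave no call by limma or edgeR (adjusted p = 0.772). Cxcl2, Ctsh, Aqp5, Cldn18, Igfbp2, H2-K1, Peg10, Impact, Slc38a4, Hmga1, Mcm3, Pola1, Dcn, Slc12a2, Scnn1b and Fxyd3 were named here after the values were seen.

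In this comparison limma called 1046 genes higher and 797 lower at P56 among 12964 tested, at a Benjamini-Hochberg adjusted p under 0.05, with 401 and 371 of them changed at least 4-fold. With edgeR 1128 and 1081 were called, of which 1015 and 794 were shared with limma. Limma called 355 and 324 with no filter on low values, 609 and 516 without robust variance estimates and 479 and 415 with a replicate block. The DESeq2 Wald test called 606 and 610. The libraries of the 2 stages did not overlap for 56.6% of genes, against 33.3% by chance. With each of the 4 libraries left out in turn, limma called 0 genes on 1 residual degree of freedom (2003 higher and 1319 lower at an unadjusted p under 0.05 without E18.5 replicate 1, 1780 and 1221 without E18.5 replicate 2, 1035 and 967 without P56 replicate 1, 940 and 887 without P56 replicate 2). With edgeR the calls in those fits were 1512 and 1419, 1163 and 1216, 284 and 256, and 285 and 271.

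Late fetal cells at E18.5 were compared with the mean of the early stages, E13.5 and E15.5, to follow the epithelium through the late fetal period. Markers of both alveolar cell types rose and genes of cell division fell. Aqp5, the water channel of type 1 cells, went from 2.36 at E13.5 and 15.4 at E15.5 to 2056 ± 177 (SD, n = 2) at E18.5 (log2 change 8.11, SE 0.183, adjusted p = 1.65e-06). Hc, complement component C5, which is made by type 2 cells, went from 2.60 and 16.5 to 1879 ± 171 (log2 change 7.89, adjusted p = 1.65e-06). Top2a, the topoisomerase of dividing cells, fell from 591 and 454 to 10.3 ± 1.46 (log2 change -5.53, adjusted p = 2.19e-05).

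Among the other largest rises, Pon1, a serum esterase gene also listed as a club cell marker, went from 0 reads at both early stages to 305 ± 99.5, at least 716-fold higher. Igfbp6, an insulin-like growth factor binding protein gene (chromosome 15, 102144362 to 102149511), went from 0.473 and 264 to 4701 ± 831, Lyz1 from 0.00 and 3.23 to 391 ± 9.47, and Vnn3, a pantetheinase gene, from 0.00 and 2.87 to 329 ± 98.4. Among the largest falls, the replication licensing gene Cdc6 (chromosome 11, 98907801 to 98923940) went from 161 and 99.4 to 1 read over the E18.5 libraries, a ratio of 718 (counting interval 128 to 28370). The spindle gene Kif15 went to 3 reads, a ratio of 184 (62.6 to 892), and the microtubule-binding gene Nusap1 fell by 6.51 on the log2 scale. Tk1 fell by 6.04 from 443 and 567 to 7.02, and the histone gene Hist1h2ao fell by 6.21, although near-identical histone copies can share its reads. These log2 changes are against the mean of the 2 early log2 values, so a ratio of arithmetic means can differ from them.

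Alveolar markers rose as groups. Of 21 tested type 2 markers 19 rose and Etv5 fell by 1.01, the same counts as adjusted over the list alone, with a median log2 change of 4.22 (camera adjusted p = 2.87e-14; adjusted p = 0.141 with an estimated correlation). Sftpd, a collectin that binds microbes, rose by 7.04, the phosphate transporter gene Slc34a2 by 6.68 and Sftpc by 4.22. Of 22 tested type 1 markers 20 rose and Igfbp2 fell by 2.93, also adjusted over the list alone (median 3.37; camera adjusted p = 7.03e-12, and adjusted p = 0.141 with an estimated correlation). Clic5 rose by 6.84, from 0.945 and 333 to 2917, Ager, which encodes the receptor for advanced glycation end products, by 4.97 and Lmo7 by 4.49. Type 2 markers took 0.0424% of reads at E13.5 and 0.342% at E15.5, and type 1 markers 0.440% and 1.44%.

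Cell division genes fell nearly throughout. Of 23 mitosis genes 22 fell, and 23 adjusted over the list alone, with a median log2 change of -4.07, or -4.19 with bounds for genes at 0 reads (camera adjusted p = 2.11e-13; adjusted p = 0.141 with an estimated correlation). Beside Top2a and Nusap1, the proliferation marker Mki67 went from 67.8 and 98.3 to 1.14 ± 0.521 and the spindle gene Tpx2 to 2 reads, a ratio of 197 (54.3 to 1632). Of 22 DNA replication genes 20 fell, and all 22 adjusted over the list alone (median -3.62, or -3.76 with bounds; camera adjusted p = 4.63e-12, and adjusted p = 0.141 with an estimated correlation). Prim1 fell by 5.11, from 418 and 386 to 10.7 ± 0.163. Ribosomal protein genes fell by less: 8 of 32 fell, 13 adjusted over the list alone, with a median of -0.672 (camera adjusted p = 0.000196; adjusted p = 0.398 with an estimated correlation), and the list took 14.2% of reads at E13.5, 12.8% at E15.5 and 8.99% and 7.70% at E18.5. Oxidative phosphorylation genes had a median of -0.326 (camera adjusted p = 0.0154; adjusted p = 0.211 with an estimated correlation), with 3 falls of 27, Ndufa2, Ndufa4 and Atp5o, and 0 adjusted over the list alone.

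Many lipid, ion transport and stress-response genes rose by E18.5. Of 24 fatty acid and phospholipid synthesis genes 16 rose and Elovl6 and Fads2 fell, as adjusted over the list alone (median 1.42; camera adjusted p = 5.61e-06, and adjusted p = 0.211 with an estimated correlation). Scd1, a fatty acid desaturase (chromosome 19, 44394455 to 44407879), went from 34.8 at E15.5 to 1674 ± 137, Gpam, an acyltransferase gene, rose by 3.19 and Lpcat1, which makes surfactant phosphatidylcholine, by 2.62. Cholesterol synthesis genes had 9 rises of 23, also adjusted over the list alone (median 0.716; camera adjusted p = 0.00284, and adjusted p = 0.197 with an estimated correlation), among them Insig1 by 1.67. Liver X receptor pathway genes had 7 rises of 13, and 9 rises with 2 falls adjusted over the list alone. Their median was 1.16 (camera adjusted p = 0.00368, and adjusted p = 0.244 with an estimated correlation). Among them Scd1, on the fatty acid list too, rose by 6.00 and the cholesterol exporter gene Abca1 by 4.30. Ion and water transport genes had 8 rises of 17, 9 adjusted over the list alone (median 1.11; camera adjusted p = 6.91e-05, and adjusted p = 0.197 with an estimated correlation). The epithelial sodium channel gene Scnn1a rose by 5.45 and the sodium pump subunit gene Atp1b1 by 3.18. Glucocorticoid-induced genes had 12 rises of 16, also adjusted over the list alone (median 1.82; camera adjusted p = 7.21e-07, and adjusted p = 0.171 with an estimated correlation), with the transcription factor gene Cebpd up by 4.78 and the phosphatase gene Dusp1 called as well (adjusted p = 5.27e-05). Dusp1 and Zfp36, also called, are on the immediate early and heat shock list too, so the rises of these lists are not fully separate results. Immediate early and heat shock genes, which tissue digestion can also induce, had 19 rises of 20, also adjusted over the list alone (median 1.74; camera adjusted p = 5.04e-11, and adjusted p = 0.197 with an estimated correlation). Fos went from 179 and 1295 to 4150 ± 116. That list took 0.538% of reads at E13.5, 1.89% at E15.5 and 2.82% and 3.47% at E18.5.

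Many innate defence, club cell and ciliated cell genes rose by E18.5 too. Innate defence genes had 13 rises of 16, 14 adjusted over the list alone (median 2.88, or 3.01 with bounds; camera adjusted p = 1.33e-08, and adjusted p = 0.211 with an estimated correlation). The chitinase-like gene Chil1 went from 1 read to 130 ± 10.1, a ratio of 913 (163 to 36110), and the lung chemokine gene Cxcl15 rose by 4.98. MHC class I genes had 6 rises of 14, also adjusted over the list alone (median 0.808; camera adjusted p = 0.00574, and adjusted p = 0.211 with an estimated correlation), including Psmb8 by 3.34. Interferon-stimulated genes had 7 rises and 1 fall, Ifitm3, of 15 (8 and 1 adjusted over the list alone; median 1.23; camera adjusted p = 0.0246, and adjusted p = 0.211 with an estimated correlation). Of 8 MHC class II genes Cd74 was the 1 call, by 1.52, also adjusted over the list alone (list adjusted p = 0.746). Club cell markers had 6 rises and 1 fall, Cckar, of 12, also adjusted over the list alone (median 1.74; camera adjusted p = 0.00284, and adjusted p = 0.197 with an estimated correlation), with Cbr2 up by 6.67 and Cyp2f2 by 4.12. Ciliated cell markers had 6 rises of 12, 8 adjusted over the list alone (median 1.70; camera adjusted p = 0.000705, and adjusted p = 0.197 with an estimated correlation), and the ciliogenesis factor gene Foxj1 stood at 0.236 and 56.0 early and 61.2 at E18.5. Xenobiotic and antioxidant enzyme genes had 9 rises of 19, also adjusted over the list alone (median 1.16; camera adjusted p = 0.00319, and adjusted p = 0.197 with an estimated correlation).

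Progenitor and fetal genes fell in part. Of 19 distal tip progenitor genes 8 fell and the receptor gene Fgfr2 rose (10 and 2 adjusted over the list alone; median -1.01; camera adjusted p = 0.0102, and adjusted p = 0.398 with an estimated correlation), and among them Sox11 fell by 3.37 on the log2 scale and Clu fell by 2.47. H19 fell by 4.34 from 5921 and 9692 to 373, whereas Meg3 rose by 2.30, Dlk1 by 2.02 and Gnas by 0.77. The imprinted list had 9 falls and these 3 rises of 17, with 11 falls adjusted over the list alone (median -1.13; camera adjusted p = 0.00574, and adjusted p = 0.205 with an estimated correlation). Fetal RNA-binding and let-7 target genes had 4 falls, Hmga1, Hmga2, Igf2bp3 and Trim71, and 1 rise, Arid3b, of 10 (5 and 1 adjusted over the list alone; median -0.941; camera adjusted p = 0.0319, and adjusted p = 0.338 with an estimated correlation). Vim fell by 3.83 from 2564 and 1193 to 123 ± 17.5, with the mesenchymal list not called (adjusted p = 0.366). Of 13 tested mesenchymal markers 3 rose, Col6a1 by 4.76, Eln by 3.31 and Tcf21 by 2.52, and 2 fell, including Vim. Their median log2 change was 0.53. Endothelial markers had 3 falls, Ramp2, Lyve1 and Tie1, of 7 and 1 rise, Esam, by 2.87 (4 and 1 adjusted over the list alone; median -1.65, or -1.80 with bounds; camera adjusted p = 0.0354, and adjusted p = 0.239 with an estimated correlation). The share of reads of all 16 listed endothelial markers was nevertheless higher at E18.5, at 0.00978% and 0.00986%, against 0.00608% at E13.5 and 0.00668% at E15.5. Epithelial identity genes had 6 rises of 12, led by Krt19 (by 2.21), while Epcam fell by 1.37 (7 and 1 adjusted over the list alone; median 0.848; camera adjusted p = 0.0192, and adjusted p = 0.338 with an estimated correlation). Etv5, Sftpc, Igfbp2, Elovl6, Fads2, Ifitm3, Cckar, Dlk1, Gnas and Igf2bp3 were named here after the values were seen.

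Limma called 2043 genes higher and 1736 lower at E18.5 than at the early stages, with 731 and 720 changed at least 4-fold. The calls of edgeR were 2340 and 1813, of which 2035 and 1660 were shared. The 2 early libraries have no replicates and were assumed to vary like the replicated stages, and more genes were lower than higher with library size alone (1726 higher and 2112 lower), with no filter on low values (1352 and 2267) and with a pseudocount of 10 (1768 and 1891). Without E13.5 limma called 959 and 644, with 12 calls of opposite sign to those above, and with each E18.5 or P56 library left out in turn it called 0 (2479 higher and 2227 lower at an unadjusted p under 0.05 without E18.5 replicate 1, where edgeR called 2631 and 2078).

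The single P14 library was compared with E18.5 to bracket birth. MHC class II, lysozyme and surfactant genes rose, and some imprinted and fetal RNA-binding genes fell. H2-Eb1 was at 3544 against 5.37 ± 5.47 (SD, n = 2) at E18.5 (log2 change 9.45, SE 0.702, adjusted p = 0.00162), and Cd74 at 535 against 5.91 (adjusted p = 0.000495). Lyz2 rose 23.8-fold to 1659 (adjusted p = 0.000813) and Sftpc 4.24-fold to 15516 (adjusted p = 0.00452). H19 fell from 373 to 7.15 (adjusted p = 0.000302), and Dlk1 from 174 to 2 reads, a ratio of 316 (counting interval 87.2 to 2613; adjusted p = 0.000495).

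Among the largest changes of abundant genes, H2-Ab1 and H2-Aa rose from 0 reads to 128 and 116, at least 224-fold and 202-fold. Rabac1, a prenylated Rab acceptor gene (chromosome 7, 24969752 to 24972754), stood at 2484 at P14 against 39.6 at E18.5, and Cox6a2 at 206 against 5.56. Msln fell 54.2-fold, Ass1, which makes argininosuccinate, 50.1-fold from 3099 ± 170 to 61.9, Gipr, an incretin receptor gene, 40.6-fold and Igf2bp3 39.7-fold. Type 2 markers had 14 rises and 0 falls of 21, 18 adjusted over the list alone (median log2 change 1.43; camera adjusted p = 1.31e-13, and adjusted p = 0.298 with an estimated correlation), with Sftpa1 up 8.29-fold and Hc 4.80-fold. MHC class II genes had 6 rises of 8, all 8 adjusted over the list alone (median 5.45; camera adjusted p = 8.22e-09, and adjusted p = 0.298 with an estimated correlation). Innate defence genes had 9 rises of 16, 12 adjusted over the list alone (median 2; camera adjusted p = 1.09e-08, and adjusted p = 0.378 with an estimated correlation), including Lyz1 at 9.67-fold and Wfdc2 at 6.35-fold. Xenobiotic and antioxidant enzyme genes had 3 rises of 19, Aox3 (9.59-fold), Ephx1 (12.5-fold) and Ces1d, and 6 adjusted over the list alone (median 0.683; camera adjusted p = 0.0343, and adjusted p = 0.378 with an estimated correlation).

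The list of type 1 markers was not called between E18.5 and P14 (median -0.177, camera adjusted p = 0.091), with 1 rise and 3 falls of 22. Lmo7 fell by 1.31 on the log2 scale, Gprc5a by 1.25 and Timp3 by 1.15 while Igfbp2 rose from 2.67 to 34.7 (7 falls and 2 rises adjusted over the list alone). The imprinted list had 7 falls and 0 rises of 17, 9 adjusted over the list alone (median -1.26; camera adjusted p = 6.82e-05, and adjusted p = 0.298 with an estimated correlation), with Meg3 down 7.95-fold and the growth factor gene Igf2 down to 2 reads, a ratio of 86.2 (23.6 to 716). Igf2bp1 and Igf2bp3 were the 2 falls among 10 fetal RNA-binding and let-7 target genes, with 3 adjusted over the list alone (median -1.09, or -0.894 with bounds; camera adjusted p = 0.00218, and adjusted p = 0.378 with an estimated correlation). Krt19 fell 7.18-fold, Cldn4 26.9-fold and Krt8 3.14-fold, which were the 3 falls among 12 epithelial identity genes, with 4 adjusted over the list alone (median -0.642, or -0.386 with bounds; camera adjusted p = 0.000843, and adjusted p = 0.378 with an estimated correlation). Cholesterol synthesis genes had 2 falls of 23, Stard4 and Insig1, and 3 adjusted over the list alone (median -0.502; camera adjusted p = 0.00012, and adjusted p = 0.298 with an estimated correlation). Ciliated cell markers were called as lower (median -1.28; camera adjusted p = 0.000415, and adjusted p = 0.334 with an estimated correlation), with Foxj1 down from 61.2 to 11 and Tppp3 up 2.79-fold, and 4 falls adjusted over the list alone with 1 rise. Immediate early and heat shock genes had 4 falls, Zfp36, Dnajb1 and the near-identical pair Hspa1a and Hspa1b, and 1 rise, Klf2, of 20 (10 and 2 adjusted over the list alone; median -0.597; camera adjusted p = 0.000415, and adjusted p = 0.418 with an estimated correlation). Endothelial markers were called as higher (median 1.68, or 1.95 with bounds; camera adjusted p = 0.00218, and adjusted p = 0.347 with an estimated correlation), with 1 rise of 7, Lyve1, and 5 adjusted over the list alone. Csf1r, a macrophage receptor gene, was the 1 call among 5 immune markers, at 22.3 against 1 read at E18.5 (ratio 117, counting interval 20.4 to 4679). Sftpc and Dnajb1 were named here after the values were seen.

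Limma called 242 genes higher and 161 lower at P14, with 153 and 103 changed at least 4-fold. The calls of edgeR were 417 and 306, which held all of limma's 242 and 161. The libraries did not overlap for 72.9% of genes against 66.7% by chance. P14 has 1 library, assumed to vary like the replicated stages, and limma called 3 and 3 genes without robust variance estimates, where 37 of the 42 genes named here lost their call, and 7 and 9 with a replicate block. With each E18.5 or P56 library left out in turn limma called 0 (1488 higher and 889 lower at an unadjusted p under 0.05 without E18.5 replicate 1), while edgeR called 925 and 780 without E18.5 replicate 1, 647 and 595 without E18.5 replicate 2, 59 and 42 without P56 replicate 1 and 76 and 55 without P56 replicate 2.

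P56 was compared with the P14 library to follow the epithelium from the suckling to the adult lung. Among type 1 markers, Rtkn2 fell from 161 at P14 to 6.47 ± 0.908 (SD, n = 2) at P56 (log2 change -4.45, SE 0.327, adjusted p = 0.00363) and Clic5 from 1498 to 232 ± 7.93 (adjusted p = 0.00363). Fbln5, an elastic fibre gene (chromosome 12, 101746565 to 101819055), fell from 2695 to 91.7 ± 22.5 (adjusted p = 0.00132), and Lox, which crosslinks collagen and elastin, from 207 to 4.78 ± 1.94 (adjusted p = 0.00363). Cxcl2, a neutrophil chemokine gene, rose 33.0-fold from 6.05 to 199 ± 42.2 (adjusted p = 0.00363), and its close copy Cxcl3 32.5-fold.

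Of 22 type 1 markers 13 fell, 19 adjusted over the list alone, and none rose (median log2 change -2.31; camera adjusted p = 1.15e-23, and adjusted p = 0.201 with an estimated correlation). Besides Rtkn2 and Clic5, the surface protein gene Pdpn fell 33.5-fold, the anchoring protein gene Akap5 13.9-fold and the semaphorin gene Sema3e 11.8-fold, while Aqp5 was at 3140 and 2772 (log2 change -0.18, adjusted p = 0.879). Other large falls were Rabac1, 29.9-fold, and Akap2, 15.9-fold. Eln, 59.1-fold, and Vim, 3.23-fold, were the 2 falls among 13 mesenchymal markers, with 5 adjusted over the list alone (median -0.783; camera adjusted p = 0.00146, and adjusted p = 0.261 with an estimated correlation). Sox9 fell 40.1-fold and Shh 3.80-fold, and the chaperone gene Clu rose 4.28-fold. Scnn1g fell 29.9-fold, Fxyd3, a sodium pump regulator gene, 6.83-fold, and Aqp1 to 0 reads, at least 82.9-fold lower, within an ion and water transport list that was not called (adjusted p = 0.0711). H19 fell to 0 reads, at least 15.7-fold lower, and Meg3 8.69-fold, the 2 falls among 17 imprinted genes (8 falls and 2 rises adjusted over the list alone; median -0.632; camera adjusted p = 0.00474, and adjusted p = 0.261 with an estimated correlation). Tnfsf9, a T cell costimulatory ligand gene, rose 9.82-fold and the lysophospholipid transporter gene Mfsd2a 8.97-fold. Pon1, 4.58-fold, was the single call among 12 club cell markers (6 adjusted over the list alone; median 0.897; camera adjusted p = 1.7e-05, and adjusted p = 0.261 with an estimated correlation). Foxj1, 6.36-fold from 11, was the single call among 12 ciliated cell markers (10 adjusted over the list alone; median 1.87; camera adjusted p = 3.43e-08, and adjusted p = 0.261 with an estimated correlation).

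Several lists were called with 0 or 1 of their members called by limma. Cholesterol synthesis genes had a median log2 change of 0.914 (camera adjusted p = 1.07e-12; adjusted p = 0.201 with an estimated correlation) with 0 of 23 called by limma, 15 adjusted over the list alone and 1 with edgeR, Fdps, which stood at 33.0 and 92.7. Immediate early and heat shock genes had a median of 0.659 (camera adjusted p = 1.37e-09; adjusted p = 0.261 with an estimated correlation) with 0 of 20 called, 11 adjusted over the list alone and 3 with edgeR. Innate defence genes had a median of 0.721 (camera adjusted p = 9.84e-06; adjusted p = 0.268 with an estimated correlation) with 0 of 16 called, 1 adjusted over the list alone and 1 with edgeR. Scd1, 2.51-fold, was the 1 fatty acid synthesis gene called of 24, with 2 adjusted over the list alone (median 0.379; camera adjusted p = 0.00786, and adjusted p = 0.394 with an estimated correlation), and Prim1, 3.83-fold, the 1 DNA replication gene of 22, also adjusted over the list alone (median 0.228; camera adjusted p = 0.0241, and adjusted p = 0.261 with an estimated correlation). Type 2 markers had a median of 0.306 (camera adjusted p = 0.00147; adjusted p = 0.261 with an estimated correlation) with 0 of 21 called by limma, over the list alone or by edgeR, and Sftpc at 15516 and 20718 (adjusted p = 0.553). MHC class II genes had 0 of 8 called in any of these ways (list adjusted p = 0.106).

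The other lists called here had 0 members called by limma. Glucocorticoid-induced genes had a median log2 change of 0.599, with 3 rises and 1 fall of 16 adjusted over the list alone and as many with edgeR (camera adjusted p = 0.00139; adjusted p = 0.261 with an estimated correlation). MHC class I genes had a median of 0.538, with 0 of 14 called over the list alone or with edgeR (camera adjusted p = 0.00679; adjusted p = 0.261 with an estimated correlation). Xenobiotic and antioxidant enzyme genes had a median of 0.357, with 0 of 19 called over the list alone and 1 with edgeR (camera adjusted p = 0.0166; adjusted p = 0.261 with an estimated correlation). Fetal RNA-binding and let-7 target genes had a median of -0.709, with 2 falls of 10 adjusted over the list alone and 0 with edgeR (camera adjusted p = 0.00146; adjusted p = 0.261 with an estimated correlation). Endothelial markers had a median of -1.30, with 2 falls of 7 adjusted over the list alone and 1 with edgeR (camera adjusted p = 0.019; adjusted p = 0.261 with an estimated correlation). This comparison shares the single P14 library with P14 against E18.5. The ciliated, cholesterol synthesis, immediate early and heat shock, and endothelial lists were called in opposite directions in those comparisons. In P56 against E18.5 none of them was called (camera adjusted p = 0.0552, 0.0525, 0.842 and 0.244, in that order). A trait of the P14 library thus cannot be told apart from a change at that age. Aqp5 and Sftpc were named in this comparison after the values were seen.

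**Figure D3:**
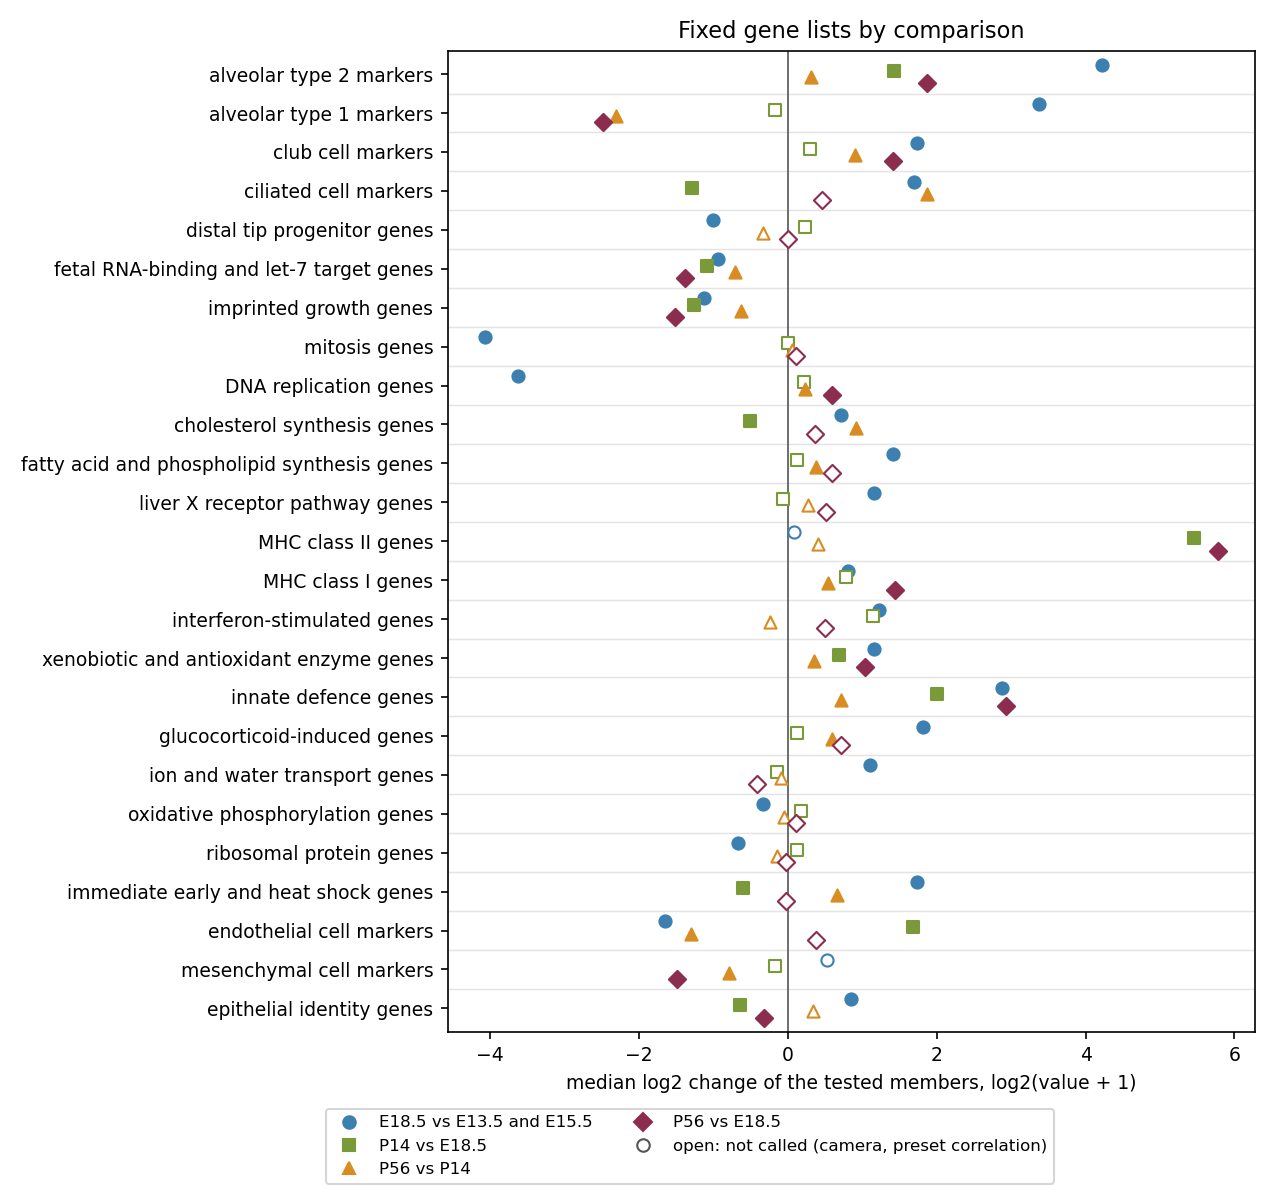
Median log2 change of the tested members of each fixed gene list that was called in at least 1 comparison, with 1 symbol per comparison, filled where camera with a preset correlation called the list and open where it did not. Type 1 markers lie at 3.37 for E18.5 against the early stages, -0.177 for P14 against E18.5, -2.31 for P56 against P14 and -2.48 for P56 against E18.5, and no filled symbol was kept with an estimated correlation.

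Limma called 16 genes higher and 90 lower at P56 than at P14, so that 15.1% of calls were higher, and edgeR 94 and 210, or 30.9% higher, with 15 and 90 shared. The counts depended strongly on the filter on low values, and limma called no gene with a replicate block, as given below. P14 has 1 library, assumed to vary like the replicated stages, and without robust variance estimates limma called 0 genes (670 higher and 718 lower at an unadjusted p under 0.05). With each E18.5 or P56 library left out in turn limma called 0 (691 and 665 at an unadjusted p under 0.05 without E18.5 replicate 1), and edgeR called 395 and 447 without E18.5 replicate 1, 382 and 445 without E18.5 replicate 2, and 0 higher and 2 lower without either P56 replicate.

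E15.5 and E13.5 have 1 library each, so they were compared without a test, as a description of these 2 libraries. Sftpc was higher at E15.5, at 1260 against 29.5, a ratio of 42.7 (95% counting interval 35.7 to 51.4), and Clic5 at 333 against 0.945, a ratio of 352 (137 to 1290). Igfbp6 was at 264 against 2 reads, a ratio of 560 (154 to 4630), the iron carrier gene Trf at 120 against 2 reads, a ratio of 254 (69.7 to 2100), and Clic3 at 520 against 8.03, a ratio of 64.7 (46.1 to 93.7). Atp6v0a4, a proton pump subunit gene, was at 226 against 0 reads, at least 319-fold higher. Guca2b, which encodes uroguanylin (chromosome 4, 119656607 to 119658954), was at 385 at E13.5 and 0 reads at E15.5, at least 358-fold lower. Rabac1 was 59.7-fold lower at E15.5 (38.1 to 99.3), the cartilage collagen gene Col2a1 14.3-fold (10.3 to 20.4), the actin-associated gene Palld 10.2-fold (6.98 to 15.6), the intermediate filament gene Nes 7.04-fold (5.54 to 9.06) and the embryonic tight junction gene Cldn6 5.86-fold (5.15 to 6.68). In all, 746 genes were at least 2-fold higher and 549 at least 2-fold lower, among 7186 with a value of at least 10 in 1 of the libraries. With a pseudocount of 10 these counts were 414 and 206.

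By list, type 2 markers had a median log2 difference of 2.74 with 20 of 21 members higher at E15.5, and type 1 markers 1.73 with 19 of 22 higher, each at percentile 100 among 10000 random lists of like size and expression. Immediate early and heat shock genes (median 1.61, 20 of 20 higher), ciliated cell markers (1.43, 12 of 12) and mesenchymal markers (1.82, 10 of 13) also stood at percentile 100, with Fos at 1295 against 179 and Col3a1 at 77.1 against 7.80, examples chosen after the values were seen. The share of reads of the 20 mesenchymal markers was nevertheless lower at E15.5, at 0.155% against 0.285%, and Vim was at 1193 against 2564 (chosen in the same way). Cholesterol synthesis genes were at the other end, at percentile 0 (median -0.605, 19 of 23 lower), with Sqle at 65.7 against 157 (chosen in the same way), as were fetal RNA-binding and let-7 target genes at percentile 0.06 (median -0.801, 8 of 10 lower), with Hmga2 at 13.3 against 66.9, also chosen after the values were seen. Mitosis genes had a median of 0.0345 at percentile 63.0 and DNA replication genes -0.238 at percentile 9.07. None of these differences has a replicate check, and the counting intervals leave out variation between animals.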

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

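Counts of calls are given as higher and lower, and the cause of each shift was not tested except where named. With no filter on low values, where more genes are tested, P56 against E18.5 gave 355 and 324, E18.5 against the early stages 1352 and 2267, P14 against E18.5 816 and 235, and P56 against P14 110 and 690. With at least 10 CPM in 2 libraries, P14 against E18.5 gave 376 and 241 and P56 against P14 57 and 136. With a pseudocount of 0.1 those comparisons gave 80 and 55, and 9 and 55, and with a pseudocount of 10 P56 against P14 gave 25 and 84. Without robust estimates limma called 609 and 516 for P56 against E18.5, 3 and 3 for P14 against E18.5 and 0 and 0 for P56 against P14. For P14 against E18.5, edgeR called 417 and 306, its legacy fit 410 and 276 and its fit without robust estimates 396 and 290. For P56 against P14 these fits called 94 and 210, 74 and 193, and 88 and 195. Limma-voom called 39 and 106 in P56 against P14. The DESeq2 Wald test called 606 and 610 in P56 against E18.5, 1401 and 973 in E18.5 against the early stages and 54 and 130 in P56 against P14. In E15.5 against E13.5 a pseudocount of 10 left 414 genes at least 2-fold higher and 206 lower. Camera with an estimated correlation called 0 lists in each of the 4 tested comparisons, against 12 of 28 in P56 against E18.5 at the preset correlation. That setting gave simulated raised lists a camera p of only 0.00717 to 0.0536, so the lost calls do not decide whether a list changed. Calls were also lost where the estimated correlation lay below the preset 0.01. For type 1 markers in P56 against E18.5 it was -0.00574, and camera p before adjustment went from 3.15e-17 to 0.0114.

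Over the libraries left out in turn, P56 against E18.5 gave 0 to 1512 higher and 0 to 1419 lower, E18.5 against the early stages 0 to 2631 and 0 to 2171, P14 against E18.5 0 to 925 and 0 to 780, and P56 against P14 0 to 395 and 0 to 447. The values of 0 come from limma with 1 residual degree of freedom and, for genes higher in P56 against P14 without either P56 replicate, also from edgeR, and a lone library was then assumed to vary like the other stages. DESeq2 size factors, library size alone and TMM kept every count within 1.5 times. Libraries of E18.5 and P56 share only replicate numbers, which the labels do not tie to a litter or day. Their deviations had a correlation of 0.00982 over 12964 genes and -0.037 over 6807 genes with a mean of at least 10. A replicate block, which leaves fewer degrees of freedom, called 479 and 415, 1121 and 772, 7 and 9, and 0 and 0 in the 4 comparisons in the order above (497 higher and 590 lower at an unadjusted p under 0.05 in P56 against P14).

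No call of a gene named in the text reversed among those refitted. Of all calls in E18.5 against the early stages, however, 12 changed sign with limma, and 11 with edgeR, without E13.5 replicate 1. Changes in the direction of a list were not counted. Of 5080 values of 216 named gene results under the alternatives, 3736 kept their side of the threshold, 1333 lost the call and 11 gained one. Direction was compared only where a gene was called in the main or the alternative fit. Of 1491 values of 112 list results, 1377 kept their side of the threshold whatever their direction, 90 lost the call and 24 gained one. Alternatives for E15.5 against E13.5 genes and lists and for the transitional list were added after the data were seen. There, 58 of 85 values of 17 genes and 135 of 140 list medians stayed within their 95% intervals, and the others moved without a change of direction. All 15 values of the transitional list kept their side of the threshold.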

Other observations

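Of the tests below, those on scaling, fewer type 1 cells, depth and female mice were chosen after the results were seen, and those on the sex makeup of the calls and on transitional genes before their results. The tests of the transitional list against single stages were added after. All genes named in this part were chosen after the values were seen. Krt7, Krt19, Cldn4 and Msln were all highest at E18.5. Krt7 stood at 1634 at E13.5, 3323 at E15.5, 11315 and 15794 at E18.5, 7596 at P14 and 2129 and 1728 at P56. Such keratins also mark a transitional alveolar state after adult lung injury, so other genes of that state may peak at E18.5 too. Over 23 tested members of a list of that state, the median log2 difference of E18.5 from the mean of the early fetal and P56 stages was 1.06, with 12 higher and 1 lower (camera adjusted p over this and the type 1 list = 2.14e-05, and adjusted p = 0.0425 with an estimated correlation). Ctgf, a matricellular target of Hippo signalling, was at 206 and 345 at E13.5 and E15.5, 793 and 900 at E18.5, 287 at P14 and 45.5 and 42.1 at P56. Tnfrsf12a went the other way (log2 difference -1.24). That contrast leaves out P14 and does not by itself show a peak. Against single stages the median log2 difference of E18.5 was 2.03 for E13.5, 1.14 for E15.5, 0.569 for P14 and 0.622 for P56 (camera adjusted p over the 4 stages = 0.000123, 0.000156, 0.000203 and 0.00559). With an estimated correlation none of the 4 was called, at adjusted p = 0.0703 for P14 and adjusted p = 0.0922 for P56. Both E18.5 libraries were above all others for only 9 of the 23 members, against 11 of 22 type 1 markers and 10.2% of all tested genes. A peak is thus neither shared by all members nor particular to this list.

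The fall of type 1 markers from E18.5 to P56 could come from the scaling, which shifts all genes of a library alike. Their median minus that of all tested genes was -2.54 (95% interval -3.71 to -1.87), and 21 of 22 lay below the median of all genes, which speaks against scaling for their level relative to other genes. RNA per cell was not analysed here. Fewer type 1 cells among the sorted P56 cells might lower all markers alike. Their log2 changes had an SD 6.38 times their median standard error, so they did not fall alike, and Aqp5 was at 2056 and 2772. Other sorted cells may also express some of them, and the question stays open.

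The 4 Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d had 2 reads over both P56 libraries, against 220 expected from their share at E18.5, so lower depth is not the cause. Female P56 mice, beside pools with males at the other stages (27 to 211 reads per library), are in line with those 2 reads and with 2289 and 1751 Xist reads. Sex makeup could then drive part of the calls in P56 against E18.5, and these 4 genes are among them. Other comparisons share such a difference. P14 had 129 Y-linked reads against 1 and 1 in the P56 libraries, and E15.5 had 27 against 211 at E13.5. The part of sex makeup in those comparisons was not tested. For P56 against E18.5, genes on the sex chromosomes were 3.59% of called and 3.17% of other tested genes with a known chromosome (odds ratio 1.14, 95% interval 0.846 to 1.51, Fisher exact p = 0.373). The odds ratio lay below the bound set beforehand as speaking against sex makeup as a main source of the calls. Its interval, a stricter rule applied later, reached just past that bound. The test also counts only X- and Y-linked genes, so the question stays open.

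Some values belong to single libraries and are given as such. Guca2b was at 384.9 at E13.5 and 0 elsewhere. Rabac1 was at 406.7, 6.817, 38.12, 41.07, 2484, 79.68 and 86.48 in order of age. Actc1 and Myl3, heart muscle genes, were at 31.09 and 13.76 at P14, and Actc1 was also at 3.229 at E15.5. Foxj1 and Dnajb13 were at 11 and 12.1 at P14, against 55.06 to 73.2 and 43.12 to 69.72 at E15.5, E18.5 and P56.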
